A study of Mus musculus with 12 samples.

How the data were processed

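Poly(A)-selected RNA of whole aortae was measured in 12 libraries, 6 per group, from C57BL/6 mice aged 7 weeks. Per the labels' protocols, fat was dissected away, RNA was extracted with Trizol, strand-specific libraries were made with a KAPA kit and both ends were read on a NovaSeq. FastQC, cutadapt, HISAT2 and StringTie are named with the GRCm38 build, per the submitters' processing notes. Their versions, settings, use of strand and the annotation release are not given in the sources used here. The authors deposited 1 table of FPKM values per transcript, 22699 transcripts by 12 libraries. Each listed transcript has a mean of at least 0.5 FPKM in the higher group, so transcripts below that in both groups are not analysed here, and FPKM summed over listed transcripts does not show depth. Depth per library is therefore unknown, and no counting interval or detection limit was computed. Because FPKM divides by the total of a library, a few abundant genes can shift all others; the median log2 difference of all tested genes was -0.024.

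Transcripts were assigned to genes through GENCODE release M21 on GRCm38, which may not be the release the authors used. In all 21493 identifiers matched with their version, 1162 with another version and 44 not at all. The last hold 0.117% of the FPKM and entered only the transcript test. The value of a gene is the sum of its listed transcripts; 12287 genes were formed, 6763 of them from 1 transcript. Coordinates are those of the gene in that annotation, from 1. Near-identical copies and overlapping or antisense genes can share reads, and how the authors split them is not given in the sources used here. No pair of libraries was a copy: 2.34% to 6.99% of genes lay within 1% of each other over all pairs of libraries.

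Groups came from the labels. Genes with at least 0.5 FPKM in at least 6 libraries were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean trend) on log2(FPKM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. A 2-fold change is a log2 difference of at least 1 on that scale. Transcripts were tested in the same way. Isoform shares were tested with limma on the arcsine square root of each transcript's share of its gene, for genes with at least 1 FPKM in every library and at least 2 transcripts with a mean of at least 0.5 FPKM. The design had allowed for a table of counts with a count test; since the table holds FPKM, the limma test named for that case was used. Fixed before the data were examined were the tests, the alternatives, 33 gene lists (21 processes and 12 cell types) and the rule for named genes. Lists with at least 5 tested members were tested with camera of limma, with a preset correlation of 0.01 between genes and adjustment over all lists. Camera with an estimated correlation and fry were run beside it. The 33 lists comprise glucocorticoid, FoxO, PPAR, fatty acid, ketone, cholesterol, clock, matrix, endoplasmic reticulum, ATF4, inflammation, interferon, autophagy, respiratory chain, ribosome, early response, antioxidant, tone, heat shock and cell cycle genes. The rest are markers of smooth muscle, endothelium, fibroblasts, brown and white adipocytes, skeletal and cardiac muscle, macrophages, lymphocytes, erythroid, Schwann and mesothelial cells.

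The rule for named genes takes the 12 largest increases and 12 largest decreases among genes past the threshold with a mean of at least 1 FPKM, up to 4 members of each list with the smallest p, and these genes regardless of outcome: Pdk4, Angptl4, Cpt1a, Fkbp5, Per1, Nos3, Acta2, Myh11, Eln, Col1a1, Ucp1 and Adipoq, beside 1 that, like a few others of the rule, is not reported here. It named 150 genes, of which the text describes a part that was chosen after their values were seen. The 6 whose call was lost when 1 library was left out are all given. Other list members, such as Scd1, Hspa5, Xbp1, Irs2 and Insr, were also picked after their values were seen. The tests were run on simulated data made from the means and spreads within groups of these libraries. Each gene, transcript or share was drawn independently, without correlation between genes or trends within libraries. The shares of unchanged calls below may thus not carry over to the real data. For each fold change, 66 or 67 genes or transcripts with a mean of at least 2 FPKM were changed, far fewer than the 3821 genes called here. Recovery of lower ones was not measured. Of genes changed 1.25-fold, 1.5-fold and 2-fold, 41.8%, 88.1% and 93.9% were recovered among 12063 genes, and 5.70% of the calls were unchanged genes. For 20599 transcripts the shares recovered were 22.4%, 52.2% and 72.7%, with 5.77% of calls unchanged. Of 14107 isoform shares, 200 with means of 20% to 60% were raised by 10, 20 or 30 points. Of these 0%, 24.5% and 46.0% were recovered. The median SD within groups of shares in that range was 11.8 points, so most changes of these sizes in such shares would be missed. Shares with a smaller spread were not simulated apart.

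Alternatives changed the pseudocount, the filter, the scaling (median-of-ratios factors, quantile normalization), the variance model, the library weights, the test (exact rank sum), the use of the most abundant transcript alone, adipocyte marker means as covariates, the replicate number as a block, and the libraries used, leaving out each in turn. Removal of a trend with transcript length and the omission of fasted replicates 5 and 6 together were added after seeing the data. The labels give no technical batch. Figures and tables were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Left out were count tests, which FPKM does not allow, and any search for variants or splice junctions, which needs reads.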

Results

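RNA of mouse aortae was sequenced from 12 aorta samples of C57BL/6 mice aged 7 weeks, 6 labelled control and 6 labelled as fasted for 24 h. The comparison asks which genes differ in aortic abundance after the fast. The table listed 22699 transcripts in FPKM (fragments per kilobase of transcript, scaled to the library total), which formed 12287 genes. The listed transcripts summed to 299588 to 327492 FPKM per library, and 21853 to 22197 of them were above 0. The number of reads behind each library is unknown. The labels do not state that the replicates came from separate animals, so p-values measure the spread between these samples, part of which may be technical. Levels are means ± SD over 6 libraries per group, and differences are fasted minus control on the log2(FPKM + 1) scale ± SE from limma, which understates the change of low genes.

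Fasted aortae held more RNA of genes that glucocorticoids and fasting induce and less RNA of genes of cholesterol synthesis and uptake and of endoplasmic reticulum stress. Mt2, a metal-binding metallothionein, rose 7.13-fold, from 41.7 ± 13.8 to 297 ± 44.01 FPKM (adjusted p = 1.30e-06). Pdk4, a kinase that inhibits the pyruvate dehydrogenase complex, rose 5.42-fold from 5.34 ± 1.82 to 28.9 ± 7.36 FPKM (adjusted p = 3.14e-06). Sqle, which encodes squalene epoxidase, was 3.16-fold lower, from 13.98 ± 2.35 to 4.43 ± 0.437 FPKM (adjusted p = 1.28e-06). The chaperone gene Calr was 2.36-fold lower, from 392 ± 28.3 to 166 ± 8.99 FPKM (adjusted p = 8.66e-08). In these 4 genes every fasted library lay outside the range of the 6 controls. Of 12063 genes tested with limma, 3821 (31.7%) passed an adjusted p of 0.05, 1667 higher and 2154 lower in the fasted group. Most changes were small: 126 genes changed at least 2-fold on the log2(FPKM + 1) scale, 80 up and 46 down. The groups did not overlap in 2053 genes, 17.02% of those tested, against 0.216% by chance. The first principal component separated the groups and held 32.8% of the variance. The second, with 12.8%, set fasted replicate 3 apart. The 2-fold count depends on the pseudocount: it was 299 with 0.1 (159 up and 140 down) and 318 with 0.01 (162 and 156), so the excess of increases does as well. Which direction prevails among all changed genes depends on the scaling, with 1974 higher and 1943 lower with median-of-ratios factors.

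Glucocorticoid receptor target genes rose as a group. Of 20 tested, 18 rose and none fell in limma, and 19 rose and 0 fell when adjusted over the list alone (camera adjusted p = 2.57e-15). Fkbp5, a co-chaperone of the glucocorticoid receptor (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527 on GRCm38), was at 3.41 ± 0.5397 FPKM in controls and 18.03 ± 4.08 FPKM in fasted aortae (log2 difference 2.08 ± 0.15, adjusted p = 1.33e-06). The 2 metallothionein genes rose with it, Mt1 from 95.7 ± 22.8 to 433 ± 43.2 FPKM (adjusted p = 9.17e-07) and Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) by 2.86 ± 0.20 on the log2 scale. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 42.3 ± 5.43 to 101 ± 9.92 FPKM (log2 difference 1.24 ± 0.09, adjusted p = 1.28e-06). The low-level gene Hif3a rose from 0.243 ± 0.0374 to 1.53 ± 0.206 FPKM (log2 difference 1.02 ± 0.07, adjusted p = 8.11e-07). Every fasted library exceeded all controls in these 5 genes. Per1, which also belongs to the clock genes, rose from 5.64 ± 3.16 to 14.8 ± 1.12 FPKM (log2 difference 1.38 ± 0.24, adjusted p = 9.50e-04). The groups did not overlap, but its most abundant transcript alone gave 0.51 (adjusted p = 0.607). Per1 lost its call with adipocyte covariates (1.06 against 1.38, adjusted p = 0.0596).

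Genes for burning fatty acids rose in part. Of the 24 fatty acid oxidation enzymes, 13 rose and none fell, and 14 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.15e-06). Cpt1a, which moves long-chain fatty acids towards mitochondrial oxidation, rose from 24.9 ± 3.18 to 45.3 ± 3.84 FPKM (log2 difference 0.84 ± 0.08, adjusted p = 1.29e-05). Ech1 rose from 31.4 ± 1.62 to 52.9 ± 4.91 FPKM (adjusted p = 4.45e-06). The carnitine carrier Slc25a20 rose from 10.3 ± 0.5302 to 15.01 ± 0.397 FPKM (adjusted p = 6.04e-06) and the thiolase Acaa2 from 18.4 ± 2.25 to 32.7 ± 2.73 FPKM (adjusted p = 1.49e-05). Among 13 tested PPAR target genes, 6 rose and none fell, and 6 rose and 0 fell when adjusted over the list alone (camera adjusted p = 3.13e-05). Cpt1a is on both lists. Pdk4 (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309) had a log2 difference of 2.24 ± 0.18. Acot1, whose reads its near-identical neighbour Acot2 can share, was at 0.302 ± 0.0531 FPKM in controls and 0.9198 ± 0.263 FPKM in fasted aortae (adjusted p = 4.34e-04). Angptl4, an inhibitor of lipoprotein lipase, was at 3.99 ± 2.66 FPKM in controls and 5.86 ± 1.52 FPKM in fasted aortae. It did not pass (0.56, adjusted p = 0.128), but did without control replicate 6 (0.79, adjusted p = 0.00984). With adipocyte covariates the difference of Angptl4 was -0.04 (adjusted p = 0.951). The 7 ketone body genes went both ways, 2 up and 2 down (2 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.298). Bdh2 rose (log2 0.45, adjusted p = 2.00e-04). Oxct1, the enzyme of ketone body use, fell from 173 ± 6.78 to 152 ± 9.27 FPKM (adjusted p = 0.00989). Angptl4 apart, the groups did not overlap in the genes named so far in this paragraph. Bdh1 was lower too (-0.27, adjusted p = 0.0394). The groups overlapped, and this call was lost without any of 7 single libraries (adjusted p 0.0507 to 0.0865: control replicates 1, 2, 4 and 5 and fasted replicates 1, 4 and 5). It was also lost with median-of-ratios factors (-0.24, adjusted p = 0.0675). The most abundant transcript alone did not pass for Bdh1 (-0.27, adjusted p = 0.0512). With adipocyte covariates the calls of Oxct1 (-0.09 against -0.19, adjusted p = 0.369) and Bdh1 (-0.15 against -0.27, adjusted p = 0.467) were lost.

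FoxO and insulin-repressed genes also rose, 12 of 18 with none lower, and 12 rose and 0 fell when adjusted over the list alone (camera adjusted p = 4.09e-07). The largest difference was in Pik3ip1, an inhibitor of phosphoinositide 3-kinase, from 7.49 ± 0.979 to 20.3 ± 3.03 FPKM (log2 difference 1.32 ± 0.10, adjusted p = 1.86e-06). Bnip3, a receptor of mitophagy, rose from 19.3 ± 1.701 to 34.2 ± 2.599 FPKM (adjusted p = 3.69e-06). The transcription factor Klf15 rose from 9.31 ± 3.08 to 21.1 ± 3.900 FPKM (adjusted p = 4.30e-04) and the translation repressor Eif4ebp1 from 15.8 ± 1.16 to 20.6 ± 1.45 FPKM (adjusted p = 6.25e-04). Every fasted library exceeded every control in these 4 genes. Irs2 and Insr, which act in insulin signalling and whose groups overlapped, had log2 differences of 0.66 (adjusted p = 0.00412) and 0.44 (adjusted p = 0.00326).

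**Figure D1:**
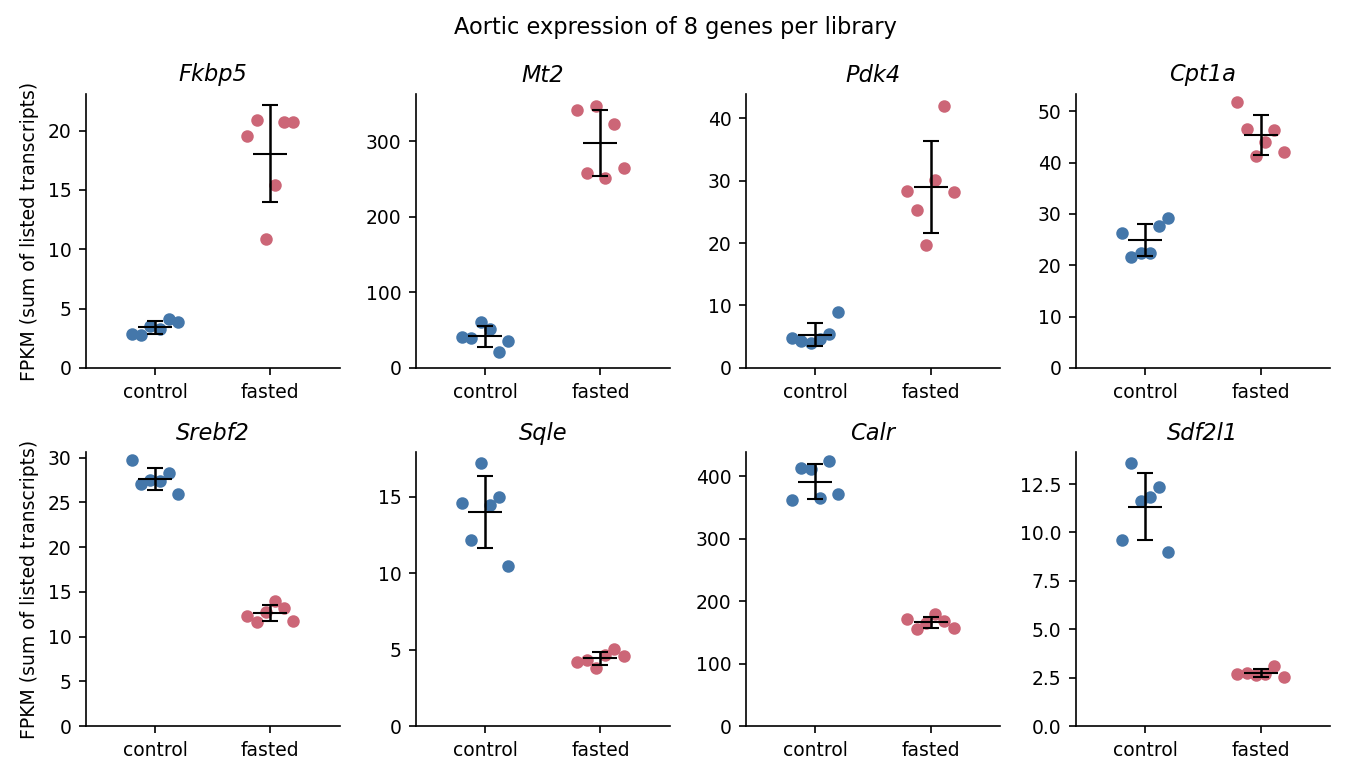
FPKM (vertical axes, sum of the listed transcripts of each gene) of 8 genes in each control and fasted library; points are libraries and bars are the mean ± SD of 6. Fkbp5, Mt2, Pdk4 and Cpt1a were higher in every fasted library than in any control, and Srebf2, Sqle, Calr and Sdf2l1 lower.

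Cholesterol genes fell nearly throughout: 21 of 25 tested genes of synthesis and uptake fell and none rose, and 0 rose and 22 fell when adjusted over the list alone (camera adjusted p = 1.33e-13). Srebf2, the transcription factor that drives this pathway, fell from 27.6 ± 1.27 to 12.6 ± 0.9004 FPKM (log2 difference -1.08 ± 0.05, adjusted p = 9.13e-08). Sqle (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192) had a log2 difference of -1.45 ± 0.10. Idi1 fell from 11.99 ± 2.46 to 3.33 ± 0.354 FPKM, Fdps from 31.5 ± 4.88 to 10.1 ± 1.901 FPKM and Cyp51 from 14.1 ± 3.46 to 4.54 ± 0.611 FPKM, with adjusted p of 1.94e-06, 3.29e-06 and 9.88e-06. In these 5 genes every fasted library lay below every control. Fatty acid synthesis genes fell as well, 13 of 19 with 1 higher, and 1 rose and 13 fell when adjusted over the list alone (camera adjusted p = 1.17e-04, but adjusted p = 0.1702 with an estimated correlation). The desaturase Scd2 fell from 48.3 ± 7.06 to 22.4 ± 1.62 FPKM (log2 difference -1.06 ± 0.09, adjusted p = 4.56e-06). The elongase Elovl5 fell from 29.9 ± 0.711 to 20.3 ± 1.18 FPKM (adjusted p = 3.20e-06). Malic enzyme Me1 fell from 31.6 ± 2.16 to 24.2 ± 1.29 FPKM (adjusted p = 2.88e-04) and Fads2 from 33.7 ± 1.49 to 26.3 ± 1.87 FPKM (adjusted p = 3.20e-04), again without overlap. The gene that rose, with overlapping groups, was Mlxipl, a carbohydrate-responsive transcription factor (log2 0.79, adjusted p = 0.0194). Scd1 had a log2 difference of 0.01 (adjusted p = 0.9803).

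Genes of the endoplasmic reticulum stress list fell, 13 of 20 with 1 higher, and 1 rose and 13 fell when adjusted over the list alone (camera adjusted p = 4.30e-09). Those with the strongest evidence encode chaperones and folding enzymes. Calr, a calcium-binding chaperone (ENSMUSG00000003814, chromosome 8, 84841850 to 84846934), had a log2 difference of -1.23 ± 0.06. Sdf2l1 (ENSMUSG00000022769, chromosome 16, 17130138 to 17132383) fell from 11.3 ± 1.73 to 2.74 ± 0.196 FPKM (log2 difference -1.71 ± 0.09, adjusted p = 1.55e-07). Creld2 fell from 29.6 ± 2.13 to 11.3 ± 1.02 FPKM (adjusted p = 1.27e-07) and the disulfide isomerase Pdia6 from 92.8 ± 6.104 to 38.7 ± 4.26 FPKM (adjusted p = 2.47e-07). The 6 fasted libraries lay below the 6 controls in these 4 genes. The transcription factor Xbp1 fell too (log2 -0.71, adjusted p = 3.78e-06), and Dnajb9, with overlapping groups, was the member that rose (0.23, adjusted p = 0.0355). Hspa5, the chaperone BiP, had a log2 difference of -0.37 and did not pass (adjusted p = 0.359).

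With the preset correlation of 0.01, camera called 9 of the 31 lists it tested, the glucocorticoid, cholesterol, endoplasmic reticulum stress, fatty acid oxidation, PPAR, FoxO, fatty acid synthesis, white and general adipocyte markers and extracellular matrix. The first 6 held with an estimated correlation: glucocorticoid targets (adjusted p = 0.0326 with an estimated correlation), cholesterol (adjusted p = 0.0374 with an estimated correlation), endoplasmic reticulum stress (adjusted p = 0.0374 with an estimated correlation), fatty acid oxidation (adjusted p = 0.0374 with an estimated correlation), PPAR targets (adjusted p = 0.0374 with an estimated correlation) and FoxO targets (adjusted p = 0.0484 with an estimated correlation). With the preset correlation, 56 of 100 splits of the 12 libraries, the real one included, gave at least as many lists, so the number 9 is not beyond chance. With the estimated correlation, a comparison chosen after that was seen, 6 lists passed in the real split and at most 1 in the other splits. Taken list by list with the preset correlation, a p as small came in 1 of 100 splits, the real one, for the glucocorticoid, cholesterol, endoplasmic reticulum stress and fatty acid oxidation lists. It came in 2 for PPAR and FoxO targets, 9 for white adipocyte markers, 11 for fatty acid synthesis and 44 for extracellular matrix. With the estimated correlation it came in 1 for fatty acid synthesis, PPAR and FoxO targets, 8 for white adipocyte markers and 44 for extracellular matrix. Chance is thus not excluded for white adipocyte markers and extracellular matrix. For fatty acid synthesis the answer depends on the correlation used.

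**Figure D2:**
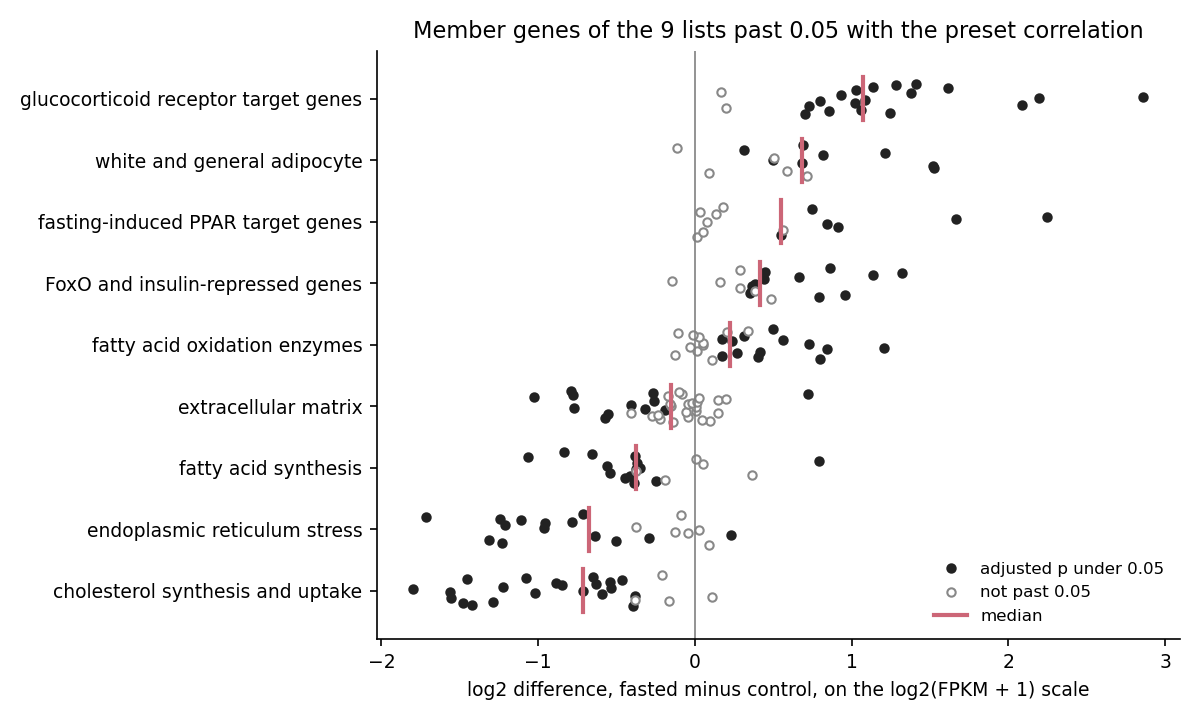
Log2 difference (fasted minus control, horizontal axis) of each tested member gene of the 9 lists that camera called with the preset correlation; filled points passed an adjusted p of 0.05 in limma and vertical bars are medians. The medians ran from -0.71 for cholesterol genes to 1.07 for glucocorticoid targets.

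Several vascular genes changed singly. Pecam1, an endothelial adhesion molecule, rose from 91.04 ± 15.7 to 155 ± 17.2 FPKM (log2 difference 0.77 ± 0.10, adjusted p = 1.63e-04). Cldn5, a tight junction gene, rose from 6.95 ± 0.874 to 12.6 ± 2.33 FPKM (adjusted p = 2.43e-04). Flt1 rose (log2 0.50, adjusted p = 4.60e-04) and Eng fell (-0.25, adjusted p = 0.003301). Of 17 endothelial markers 4 rose and 1 fell (4 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.07302, adjusted p = 0.539 with an estimated correlation). That share of called genes was near the 31.7% of all tested genes. The list passed without control replicate 2 (0.0491) or 4 (0.0103). Over all libraries, 36 of 100 splits, the real one included, gave as small a p with the preset correlation. Nos3, the endothelial nitric oxide synthase, rose from 9.54 ± 1.51 to 14.3 ± 2.09 FPKM (log2 difference 0.54 ± 0.11, adjusted p = 0.00255), with overlapping groups. Its most abundant transcript alone gave 0.26 (adjusted p = 0.279), and with adipocyte covariates it was 0.38 (adjusted p = 0.132). The epoxide hydrolase Ephx2 rose from 9.49 ± 1.12 to 18.5 ± 1.89 FPKM (adjusted p = 9.17e-06). The prostacyclin synthase Ptgis rose from 259.9 ± 20.7 to 343 ± 21.3 FPKM (adjusted p = 3.76e-04). The serotonin receptor gene Htr2a fell from 5.78 ± 1.11 to 3.14 ± 0.5997 FPKM (adjusted p = 0.00127). Cth, which makes hydrogen sulfide, was at 0.424 ± 0.09098 FPKM in controls and 0.925 ± 0.0931 FPKM in fasted aortae (adjusted p = 3.00e-04). The vascular tone list held 8 genes that rose and 3 that fell of 26 (9 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.05205, adjusted p = 0.297 with an estimated correlation). It passed without control replicate 2 (0.0491) or 4 (0.0333) or fasted replicate 1 (0.0439) or 3 (0.0272), and without the expression filter (0.0444). For the tone list over all libraries, as small a p came in 12 of 100 splits. Of 17 clock genes 5 rose and 1 fell (5 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.0746, adjusted p = 0.375 with an estimated correlation, 0.0491 without control replicate 2, 0.0444 without the expression filter). For the clock list over all libraries, as small a p came in 28 of 100 splits. Tef rose from 9.999 ± 3.19 to 19.3 ± 2.51 FPKM (adjusted p = 0.00153) and Nr1d2 from 4.803 ± 1.42 to 10.1 ± 2.45 FPKM (adjusted p = 0.00167). Npas2 fell from 30.2 ± 3.01 to 22.9 ± 2.096 FPKM (adjusted p = 0.00207). Apart from Nos3 and Nr1d2, the groups did not overlap in the genes of this paragraph. With adipocyte covariates the calls of Htr2a (-0.39 against -0.71, adjusted p = 0.101) and Tef (0.73 against 0.92, adjusted p = 0.0863) were lost.

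The contractile genes of smooth muscle, the main cell type of the aortic wall, showed little change. Acta2 was at 4984 ± 457 FPKM in controls and 4623 ± 245 FPKM in fasted aortae (adjusted p = 0.303) and Myh11 at 1129 ± 44.9 FPKM in controls and 1085 ± 59.99 FPKM in fasted aortae (adjusted p = 0.437). Of 20 markers 2 rose and 3 fell, and 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.795). Sost, an inhibitor of Wnt signalling, fell from 570.4 ± 54.7 to 305 ± 27.2 FPKM (log2 difference -0.90 ± 0.08, adjusted p = 4.56e-06). The potassium channel subunit Kcnmb1 fell from 89.8 ± 2.91 to 64.4 ± 3.26 FPKM (adjusted p = 6.91e-06) and Lmod1 rose (log2 0.32, adjusted p = 0.00359). Synpo2 (0.18, adjusted p = 0.0427) lost its call without any of 7 single libraries (adjusted p 0.0562 to 0.0904: control replicates 2, 4, 5 and 6 and fasted replicates 2, 5 and 6). Matrix genes were lower in part, 11 of 35 with 1 higher, and 1 rose and 11 fell when adjusted over the list alone (camera adjusted p = 0.0335, but adjusted p = 0.709 with an estimated correlation). P4ha1, a subunit of the collagen prolyl hydroxylase, fell from 40.9 ± 2.49 to 19.7 ± 2.596 FPKM (log2 difference -1.03 ± 0.08, adjusted p = 2.03e-06). Col6a3 fell from 101 ± 13.7 to 59.1 ± 9.39 FPKM (adjusted p = 2.41e-04). The elastic fibre gene Fbln5 fell from 266 ± 23.7 to 200.2 ± 18.1 FPKM (adjusted p = 0.00103) and Tnc from 36.8 ± 3.63 to 21.4 ± 6.38 FPKM (adjusted p = 0.00128). Eln at 1826 ± 256 FPKM in controls and 1658 ± 336 FPKM in fasted aortae (adjusted p = 0.419) and Col1a1 at 599 ± 124 FPKM in controls and 489 ± 59.97 FPKM in fasted aortae (adjusted p = 0.123) did not pass. The matrix list was lost without control replicate 2, 5 or 6 or fasted replicate 2, 3, 5 or 6, with adjusted p of 0.0559, 0.0519, 0.0521, 0.0673, 0.07796, 0.0664 and 0.0578, and without both fasted replicates 5 and 6 (0.137). Fibroblast markers moved apart, 4 up and 4 down of 12 (4 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.991). Clec3b fell from 173 ± 22.6 to 108 ± 12.9 FPKM (adjusted p = 2.40e-04) and Col14a1 from 108 ± 16.8 to 70.3 ± 8.86 FPKM (adjusted p = 0.001296). Lum fell (log2 -0.31, adjusted p = 0.0162) and Pdgfra rose (0.29, adjusted p = 0.00518). The groups overlapped in Synpo2, Tnc, Lum and Pdgfra and in no other called gene of this paragraph. The most abundant transcript alone did not pass for Synpo2 (0.11, adjusted p = 0.583). With adipocyte covariates the calls of Lum (-0.10 against -0.31, adjusted p = 0.564), Col14a1 (-0.49 against -0.61, adjusted p = 0.0645), Lmod1 (0.27 against 0.32, adjusted p = 0.109) and Synpo2 (0.27 against 0.18, adjusted p = 0.06899) were lost.

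Markers of other cell types moved with the groups or with single libraries. White and general adipocyte markers rose, 8 of 13 with none lower, and 8 rose and 0 fell when adjusted over the list alone (camera adjusted p = 3.13e-05, but adjusted p = 0.198 with an estimated correlation). Fabp4, a fatty acid binding protein also made by capillary endothelium, rose from 67.8 ± 15.6 to 195 ± 41.2 FPKM (log2 difference 1.52 ± 0.16, adjusted p = 2.32e-05). The lipid droplet gene Plin4 rose from 67.6 ± 5.69 to 119.5 ± 5.64 FPKM (adjusted p = 1.28e-06) and the glucose transporter Slc2a4 from 7.04 ± 1.02 to 12.03 ± 2.23 FPKM (adjusted p = 7.46e-04). Lipe rose (log2 0.69, adjusted p = 5.33e-04), though not in its most abundant transcript alone (0.33, adjusted p = 0.236). Adipoq, which adipocytes alone make in quantity, was at 2.97 ± 1.53 FPKM in controls and 6.25 ± 4.69 FPKM in fasted aortae. It did not pass (0.72, adjusted p = 0.164), but did without fasted replicate 6 (0.96, adjusted p = 0.04604). Of other list genes restricted to adipocytes, Cidec passed (1.53, adjusted p = 0.00421) and Plin1, Cfd, Car3 and Retn did not. Of 8 brown adipocyte markers 1 rose and none fell, adjusted over the list alone too (camera adjusted p = 0.138). Cidea was at 10.4 ± 2.202 FPKM in controls and 18.3 ± 4.997 FPKM in fasted aortae (adjusted p = 0.00342, 0.157 with adipocyte covariates, of which it is itself part). Ucp1, at 1.26 ± 2.58 FPKM in controls and 6.09 ± 6.81 FPKM in fasted aortae, did not pass (1.48, adjusted p = 0.115). Cox8b did not pass (0.95, adjusted p = 0.146) except without control replicate 6 (1.27, adjusted p = 0.0391). These markers stand beside the fatty acid oxidation, PPAR and fatty acid synthesis genes above, many of which adipocytes also express. With the brown and white marker means as covariates, which include markers that themselves rose, the count of changed genes was 2090. With the mean of 6 adipocyte-restricted genes as the covariate, a set chosen after seeing the data, it was 3479. In these adipocyte genes the groups did not overlap for Fabp4, Plin4, Slc2a4 and Lipe, and overlapped for Cidea.

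Of 8 cardiac markers, only Tnnt2 passed, at 18.6 ± 4.06 FPKM in controls and 62.8 ± 46.2 FPKM in fasted aortae (log2 difference 1.44 ± 0.37, adjusted p = 0.0105). Its most abundant transcript alone did not (0.29, adjusted p = 0.903; list camera adjusted p = 0.462; 1 rose and 0 fell when adjusted over the list alone). Fasted replicates 5 and 6 were the highest of the 12 libraries for 6 of these 8 markers, with Myh6 at 27.5 and 16.7 FPKM against 0.448 to 6.64 elsewhere. Without both, 3113 genes passed. Of 16 macrophage markers 3 rose and 1 fell, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.215, 0.0272 without fasted replicate 3, adjusted p = 0.865 with an estimated correlation). Over all libraries, 57 of 100 splits, the real one included, gave as small a p for this list with the preset correlation. Lyve1 rose from 10.8 ± 1.29 to 19.6 ± 3.44 FPKM (adjusted p = 2.24e-04) and the scavenger receptor Cd163 from 4.38 ± 0.664 to 9.76 ± 3.400 FPKM (adjusted p = 0.00942). Adgre1 (-0.46, adjusted p = 0.02896) lost its call without control replicate 2, 4 or 5 or fasted replicate 2 (adjusted p 0.0541 to 0.0619). Cd14 (0.42, adjusted p = 0.0458) lost it without any of 9 libraries, all but control replicate 4 and fasted replicates 1 and 3 (adjusted p 0.0637 to 0.0944). The groups overlapped for Cd163, Adgre1 and Cd14, but not for Tnnt2 and Lyve1. The most abundant transcript alone did not pass for Cd14 (0.42, adjusted p = 0.0614). Adgre1 lost its call with adipocyte covariates (-0.03 against -0.46, adjusted p = 0.907).

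**Figure D3:**
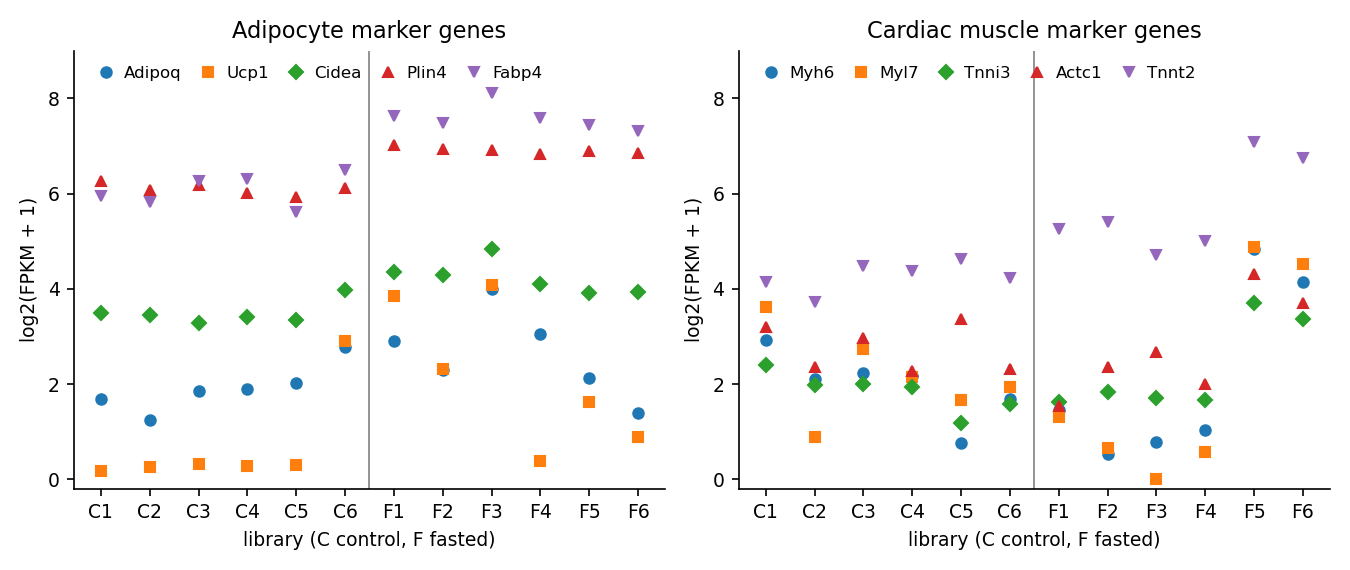
Log2(FPKM + 1) of 5 adipocyte and 5 cardiac marker genes (vertical axes) in the 6 control and 6 fasted libraries (horizontal axes), 1 point per gene and library. Fabp4 and Plin4 lay higher in every fasted library. Ucp1 reached 6.52 FPKM in control replicate 6 alone among controls, and these 5 cardiac genes were highest in fasted replicates 5 and 6.

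The other process lists did not pass, but single members changed. Since 31.7% of all tested genes passed, changed members are common in any list. Among the process lists here and in the next paragraph, only heat shock and ATF4 genes were clearly above that share. Among heat shock and cold-inducible genes 2 rose and 7 fell of 17 (3 and 8, adjusted over the list alone; camera adjusted p = 0.225). The cold-inducible RNA-binding genes Rbm3 and Cirbp rose, from 37.8 ± 7.32 to 94.9 ± 14.6 FPKM (adjusted p = 2.09e-05) and from 27.2 ± 3.63 to 57.8 ± 8.47 FPKM (adjusted p = 1.19e-05). The co-chaperones Hspe1 and Chordc1 fell (log2 -0.46, adjusted p = 0.001002, and -0.55, adjusted p = 0.00128). Among ATF4 targets 3 rose and 5 fell of 20 (3 and 5, adjusted over the list alone; camera adjusted p = 0.8402). Mthfd2, a folate enzyme of mitochondria, rose from 9.85 ± 1.39 to 23.6 ± 2.304 FPKM (adjusted p = 1.94e-06), and Atf5 fell from 105 ± 9.35 to 63.6 ± 3.57 FPKM (adjusted p = 4.38e-06). Among antioxidant genes 4 rose and 3 fell of 22 (4 and 3, adjusted over the list alone; camera adjusted p = 0.286). Gsta3 rose from 2.34 ± 0.337 to 6.43 ± 0.765 FPKM (adjusted p = 1.79e-06). For autophagy and lysosome 6 rose and 1 fell of 23 (6 and 2, adjusted over the list alone; camera adjusted p = 0.138). Sqstm1 rose from 104 ± 5.604 to 141 ± 7.87 FPKM (adjusted p = 3.82e-05) and Gabarapl1 from 75.9 ± 4.74 to 105 ± 7.78 FPKM (adjusted p = 8.34e-05). For vascular inflammation 1 rose and 1 fell of 15 (1 and 1, adjusted over the list alone; camera adjusted p = 0.226). The cytokine gene Il33 fell from 10.1 ± 0.951 to 5.24 ± 0.784 FPKM (adjusted p = 2.11e-05) and the adhesion molecule Icam1 rose (log2 0.38, adjusted p = 0.00413). For interferon response 2 rose and 4 fell of 22 (2 and 4, adjusted over the list alone; camera adjusted p = 0.795). Ifit2 rose (log2 0.61, adjusted p = 6.45e-04). Of the called genes in this paragraph the groups overlapped only for Icam1. Chordc1 lost its call with adipocyte covariates (-0.49 against -0.55, adjusted p = 0.0581).

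Among immediate early genes 5 rose and 1 fell of 23 (5 and 1, adjusted over the list alone; camera adjusted p = 0.225). Klf6 rose from 73.4 ± 8.101 to 112 ± 11.6 FPKM (adjusted p = 1.51e-04). For cell cycle genes 1 rose and 5 fell of 28 (1 and 5, adjusted over the list alone; camera adjusted p = 0.992), with a median above 0 and a mean below 0. Mcm2 fell (log2 -0.45, adjusted p = 0.00159) and Mcm7 rose (0.40, adjusted p = 0.00239). For oxidative phosphorylation 1 rose and 4 fell of 29 (1 and 4, adjusted over the list alone; camera adjusted p = 0.815). Uqcrfs1 rose (log2 0.29, adjusted p = 4.97e-04). Cycs (-0.23, adjusted p = 0.0234) lost its call without control replicate 3 or 4 or fasted replicate 1 (adjusted p 0.05005 to 0.0504). Of 26 ribosomal protein genes Rpl3 alone passed (log2 0.28, adjusted p = 0.0144; 0 adjusted over the list alone; camera adjusted p = 0.0746). The list passed without control replicate 3 (0.01303) or 4 (0.00850) or fasted replicate 1 (0.00978), with median-of-ratios factors (0.0476), and with a length trend removed, a setting chosen after seeing the data (7.01e-05). Over all libraries it had adjusted p = 0.865 with an estimated correlation, and 58 of 100 splits, the real one included, gave as small a p with the preset correlation. Of 7 Schwann cell and neuron markers 1 rose, Mal (log2 0.87, adjusted p = 2.40e-04), and 2 fell, as adjusted over the list alone (camera adjusted p = 0.912). These were Gap43 (-0.37, adjusted p = 0.00708) and Cnp (-0.25, adjusted p = 0.0361). The call of Cnp was lost without any of 8 libraries (control replicates 1, 4, 5 and 6 and fasted replicates 1 to 4; adjusted p 0.05403 to 0.0751). Of 5 mesothelial markers Krt18 rose from 13.3 ± 2.07 to 22.3 ± 2.71 FPKM (adjusted p = 3.14e-04), 1 adjusted over the list alone (camera adjusted p = 0.109). Of the others, Msln was at 15.1 and 6.79 FPKM in fasted replicates 5 and 6 (at most 4.03 elsewhere), Upk1b at 4.66 and 3.14 (at most 1.67) and Krt19 at 4.75 and 3.33 (at most 1.72). None of 6 erythroid genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.795). The globin genes are near-identical copies, so their separate levels are uncertain. Skeletal muscle had 4 tested markers, too few for camera, and none passed in limma, adjusted over the list alone too. The groups overlapped for Cycs, Rpl3, Gap43 and Cnp and for no other called gene named here. None of the lymphocyte markers is listed. With adipocyte covariates the calls of Mcm2 (-0.43 against -0.45, adjusted p = 0.0522), Cycs (-0.21 against -0.23, adjusted p = 0.179), Gap43 (-0.37 against -0.37, adjusted p = 0.0962) and Cnp (-0.15 against -0.25, adjusted p = 0.477) were lost.

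Outside the lists, the largest increases with a mean of at least 1 FPKM included Galnt15, which encodes a glycosyltransferase, from 7.66 ± 1.44 to 52.4 ± 8.79 FPKM (log2 difference 2.63 ± 0.13, adjusted p = 9.13e-08). Fam107a rose from 2.42 ± 0.648 to 18.5 ± 3.196 FPKM (log2 difference 2.51 ± 0.14, adjusted p = 2.46e-07). Trp53inp1 rose from 9.87 ± 2.69 to 43.2 ± 6.96 FPKM, Map3k6 from 2.94 ± 0.272 to 12.1 ± 1.52 FPKM and Angptl7 from 41.8 ± 9.397 to 157 ± 18.6 FPKM, with adjusted p of 2.77e-06, 8.66e-08 and 3.11e-06. The cytochrome P450 gene Cyp2e1 rose with a wide spread, from 2.94 ± 1.202 to 18.2 ± 12.2 FPKM (adjusted p = 3.80e-04). Pck1, a gluconeogenic and glyceroneogenic enzyme, rose from 1.23 ± 1.400 to 7.31 ± 4.64 FPKM with overlapping groups (log2 difference 1.90 ± 0.41, adjusted p = 0.00367). It gave 0.48 with adipocyte covariates (adjusted p = 0.284). Kank4 was the gene with the largest decrease, from 7.48 ± 1.56 to 1.02 ± 0.229 FPKM (log2 difference -2.06 ± 0.12, adjusted p = 3.48e-07). Pycr1, an enzyme of proline synthesis, fell from 9.58 ± 1.45 to 2.44 ± 0.7105 FPKM (adjusted p = 2.79e-06). Nrep fell from 30.8 ± 5.88 to 10.6 ± 1.88 FPKM (adjusted p = 9.88e-06) and the kinase gene Camk2b from 10.3 ± 3.42 to 3.202 ± 0.871 FPKM (adjusted p = 1.76e-04). Pck1 apart, every fasted library lay outside the control range in these genes.

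At the level of transcripts, 3332 of 20599 passed in limma, 1482 higher and 1850 lower. Median-of-ratios factors turned the majority, with 1688 higher and 1662 lower. In all, 340 genes had a changed transcript without passing as a gene. Few changes in the mix of isoforms passed. Of 14107 transcripts in 4947 genes, 51 in 34 genes changed their share, 36 of them by at least 10 percentage points, and 22 of the 34 genes did not pass in level. The 4 examples that follow were chosen after their values were seen. Eif4h-205 went from 48.8% ± 2.49 to 68.00% ± 2.74 of its gene (adjusted p = 0.01001). Morf4l1-202 went from 79.5% ± 1.18 to 66.4% ± 2.75 of its gene (adjusted p = 0.0121) and Mcam-201 went from 76.00% ± 1.702 to 64.9% ± 1.63 of its gene (adjusted p = 0.0203). Cdkn1a-201 went from 82.1% ± 2.07 to 93.1% ± 1.248 of its gene (adjusted p = 0.00499). Shares rest on the estimated split of reads between overlapping transcripts. The count fell to 27, 31, 31, 21 and 27 without fasted replicates 1, 2, 4, 5 and 6 in turn, and to 3 without 5 and 6 together.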

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

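The tests of perivascular fat and of Tnnt2 without the 2 cardiac-rich libraries were chosen only after the result was seen. Those of unlisted transcripts, of GC content and length, and of the second cardiac list were set before their own results. The last of the GC and length tests was set after the trends per library were known. The 3 patterns weighed here were also chosen after their values were seen. Of the genes of the rule for named genes and 10 genes named elsewhere, 155 were searched for a library far from the other 5 of its group, by Dixon's ratio on the log2 scale. In 13 of 310 groups of 6 the ratio passed its limit, close to the 1 in 20 that chance gives. Ucp1 was at 6.52 FPKM in control replicate 6, against 0.1302 to 0.245 in the other 5 libraries of the group. The same library was high in other brown fat or fasting genes, Cidea at 14.8 FPKM in control replicate 6 (8.73 to 10.3 elsewhere), Cox8b at 9.24 FPKM in control replicate 6 (0.806 to 2.35 elsewhere) and Pdk4 at 8.93 FPKM in control replicate 6 (4.03 to 5.43 elsewhere). Fasted replicate 3 was low for Cd163 at 3.40 FPKM (8.93 to 12.5 elsewhere). It was high for Cebpb at 30.4 FPKM (22.98 to 24.9 elsewhere) and Wipi2 at 16.2 FPKM (13.4 to 14.4 elsewhere). Single libraries stood apart for Angptl7 at 23.6 FPKM in control replicate 5 (41.5 to 49.5 elsewhere), Ephx2 at 14.9 FPKM in fasted replicate 6 (18.2 to 20.3 elsewhere) and Krt18 at 17.2 FPKM in fasted replicate 1 (21.9 to 25.03 elsewhere). Others were Stmn2 at 2.397 FPKM in control replicate 4 (1.62 to 1.85 elsewhere), Mcm2 at 1.54 FPKM in fasted replicate 5 (1.17 to 1.299 elsewhere) and Igf1 at 14.96 FPKM in fasted replicate 4 (10.2 to 11.2 elsewhere). Of 14 groups of values per library, fasted replicate 3 passed in a pair of them: it had 21875 transcripts above 0, against 22085 to 22197, and a mean correlation with its group of 0.9699, against 0.978 to 0.9796.

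Of 13 white and general adipocyte markers 8 were higher in the fasted group, and fat left on the vessel is a candidate explanation. Of those most restricted to adipocytes, Cidec alone passed (log2 1.53, limma adjusted p = 0.00421). Adipoq, Plin1 and Cfd were higher without passing (0.72, 0.50 and 0.59, adjusted p = 0.164, 0.205 and 0.341). Car3 and Retn differed little (0.09 and -0.11, adjusted p = 0.898 and 0.788). Adjustment for the mean of 6 adipocyte-restricted genes (Adipoq, Cfd, Car3, Retn, Plin1 and Cidec) left the median log2 difference of the other 7 called list genes at 0.75 (SD 0.35), against 0.69 before, with 7 of 7 still past the threshold in limma, for example Fabp4 at 1.33 (adjusted p = 2.78e-05). This argues against fat as the whole cause for these genes, though only weakly. The 6 covariate genes were set apart after their values were seen, and most of them had not passed. The other 7 were taken because they had passed. The other genes are also expressed outside adipocytes, and Cidec itself rose, so the adjustment is not free of fasting. Among the covariate's own genes, Cidec stayed higher after adjustment (1.00, limma adjusted p = 3.95e-05). Car3 and Retn were then lower (-0.58 and -0.50, adjusted p = 0.00402 and 0.0207), and the rest did not pass. The covariate is the mean of these 6 genes, so their adjusted differences must cancel out. Some had to come out lower once Cidec was higher, so these values only compare the 6 genes with each other. A response to fasting within aortic cells stays open and was not tested; RNA of the wall and of its fat measured apart would tell it from residual fat.

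Fasted replicate 3 was higher than the other fasted libraries in 17 of 21 adipocyte genes, with a median log2 deviation of 0.61. It was also at least 2-fold lower in 93 of 7594 genes with a mean of at least 5 FPKM, against 27 to 52 in the other libraries. Whether fat explains either part was not tested. Reads assigned to transcripts that the table does not list may contribute to the lower genes, since 67.7% of them have unlisted coding transcripts against 51.9% of the others (one-sided Fisher's exact test p = 0.00152). GC content and length may too, with Spearman correlations across genes of 0.46 and -0.35, though genes are not independent replicates. No other library reached 0.46 with GC content, but trends were not particular to this library. Control replicate 2 reached 0.34 with GC content, and control replicate 6 and fasted replicate 1 reached 0.38 and 0.42 with length. Those libraries had 45, 43 and 34 lower genes, so a trend alone did not bring as many. After removal of both trends 81 genes were at least 2-fold lower, against at most 52 in any other library before such removal, so these trends are not the whole cause. No biological explanation was tested.

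Cardiac muscle genes were high in fasted replicates 5 and 6, the 2 highest libraries for 6 of 8 first-list genes, with Myl7 at 28.5 and 22.1 FPKM. Cardiac muscle left on the aorta may account for this. In a second cardiac list the same 2 libraries were highest for 5 of 19 genes, against 1.51% per gene by chance (one-sided exact binomial p = 7.77e-06). That p takes the genes as independent, but cardiac genes vary together (estimated correlation 0.45 in the first list), so it overstates the evidence. The share of all genes with these 2 libraries highest was not computed. Several second-list genes are also expressed in smooth muscle, and the mesothelial markers Msln, Upk1b and Krt19 were highest in the same 2 libraries (Msln at 15.1 and 6.79 FPKM), so cardiac genes were not alone in this. Without both libraries Tnnt2 still differed by 0.83 ± 0.18 (SE; limma adjusted p = 0.00671), against 1.44 with them, which argues against cardiac muscle of these libraries as the whole cause for Tnnt2. No biological explanation was tested.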

How the results depend on the processing

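The removal of a length trend and the omission of both fasted replicates 5 and 6 were chosen after seeing the data. The count of changed genes, 3821, was 3101 with an exact rank sum test and 3917 with median-of-ratios factors (50.4% higher, against 43.6%). It was 4050 without the length trend, 3113 without fasted replicates 5 and 6, and 2090 with the adipocyte covariates, which shared 1807 calls with the original. That fit spends 2 degrees of freedom. Its covariates include markers that themselves rose, 8 of 13 white and 1 of 8 brown, so they overlap with the group. Some calls were lost without a clearly smaller difference, such as Gap43 (-0.37 against -0.37) and Synpo2 (0.27 against 0.18). Others were lost with a much smaller one, such as Adgre1 (-0.03 against -0.46). A lost call in that fit thus need not mean a smaller difference. The cause of the lower count was not tested. The 2-fold count of 126 became 299 with a pseudocount of 0.1 and 318 with 0.01, since a smaller pseudocount shrinks low genes less. Isoform shares fell from 51 to 3 without fasted replicates 5 and 6, with fewer samples. The 9 lists became 17 with fry, which does not compare a list with other genes (gained were ketone, clock, inflammation, autophagy, antioxidant, tone, smooth muscle and brown adipocyte), and 6 with the estimated correlation. Leaving out each library in turn gave 3331 to 4168 genes, 123 to 134 genes by at least 2-fold, 2692 to 3542 transcripts, 21 to 44 isoform shares and 8 to 12 lists. The replicate block apart, the other alternatives run kept these counts within 1.5 times. The alternative for a table of counts was not run, as the table holds FPKM.

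Equal replicate numbers showed no clear sign of pairing the libraries: the deviations of same-numbered libraries correlated at -0.01 to 0.08. Not every library correlated best with its own number. Correlations over all genes can miss a pairing that touches only part of them, so pairing is not excluded. With the replicate block 3652 genes, 2576 transcripts and 14 lists passed. The lists gained were clock and vascular tone (0.0493 each), ribosomal proteins and mesothelial markers (0.0229 each) and endothelial markers (0.0327). Of isoform shares 0 passed in limma, with 1494 at an unadjusted p under 0.05 against 1673 without the block. Among the 150 genes of the naming rule, 28 lost their call with the adipocyte covariates, 11 with the most abundant transcript alone, 4 with the block and 1 with median-of-ratios factors. A call was gained by 2 with the adipocyte covariates (Msln and Upk1b), 3 with the block (Msln, Upk1b and Rpl10a) and 1 with median-of-ratios factors (Rpl4). With 1 library left out 6 lost it (Cd14, Bdh1, Cnp, Cycs, Synpo2 and Adgre1) and 7 gained it (Adipoq, Angptl4, Cox8b, Ptgs2, Selp, Rpl4 and Rpl10a). Adipoq, itself part of the covariate, turned from 0.72 to -0.69 (adjusted p = 0.0202) with it. In their most abundant transcript alone Irgm1 (0.69 against 0.24, adjusted p = 0.369), with a larger difference, and Myc (0.22 against 0.59, adjusted p = 0.133), with a smaller one, lost their calls.

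Of 100 splits of the 12 libraries into 6 and 6, drawn from 462, the real one alone gave counts as large as its own. These were 3821 genes (highest other 55), 126 by at least 2-fold (highest other 3), 3332 transcripts (highest other 4) and 51 isoform shares (highest other 5). At 1 of 100 each, the smallest share these splits can give, such counts are unlikely by chance. The isoform count was not stable, at 3 without fasted replicates 5 and 6 and 0 with the replicate block. For the 9 lists with the preset correlation such counts were common: 56 splits, the real one included, gave at least as many, and the highest other 18. With the estimated correlation, compared after this was seen, the real split gave 6 and the others at most 1. Unknown depth limits what can be said of low genes.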

Other observations

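The 8 lists and the single genes of this part were all chosen after their values were seen, so their p-values only describe these data. Genes of the early secretory pathway were lower in fasted aortae. For translocation into the endoplasmic reticulum and N-glycosylation, 1 rose and 20 fell of 32 (1 and 21 adjusted over the list alone; camera p = 3.82e-09, p = 0.0106 with an estimated correlation). The channel subunit Sec61b fell from 82.5 ± 7.42 to 49.97 ± 3.89 FPKM (adjusted p = 1.02e-05). For the COPI and COPII vesicle coats, 0 rose and 13 fell of 19 (0 and 17 adjusted over the list alone; camera p = 4.00e-07, p = 0.0108 with an estimated correlation). Of tubulins, 0 rose and 8 fell of 11 (0 and 9 adjusted over the list alone; camera p = 1.31e-05, p = 0.111 with an estimated correlation). Ribosome biogenesis went both ways, as 3 rose and 7 fell of 30 (3 and 8 adjusted over the list alone; camera p = 0.0882, p = 0.404 with an estimated correlation).

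Cytochrome P450 and flavin monooxygenase genes were mostly higher, as 11 rose and 2 fell of 17 (12 and 2 adjusted over the list alone; camera p = 3.33e-07, p = 7.46e-04 with an estimated correlation). Fmo2 rose from 227 ± 19.9 to 455 ± 65.4 FPKM (adjusted p = 1.77e-05). Proline genes moved apart: Prodh, the first enzyme of proline breakdown, rose from 1.78 ± 0.518 to 6.28 ± 0.969 FPKM (adjusted p = 1.30e-05). Pycr1 and Aldh18a1 of proline synthesis fell by 1.63 (adjusted p = 2.79e-06) and fell by 1.02 (adjusted p = 1.79e-06) on the log2 scale. Of proline synthesis genes 0 rose and 3 fell of 4 (0 and 3 adjusted over the list alone), and of proline breakdown genes 1 rose and 1 fell of 3 (1 and 1 adjusted over the list alone), both too few for camera. Of polyamine genes 2 rose and 3 fell of 7 (2 and 4 adjusted over the list alone; camera p = 0.652, p = 0.696 with an estimated correlation). Glul, the glutamine synthetase, rose from 46.8 ± 4.36 to 126 ± 12.9 FPKM (log2 difference 1.40 ± 0.08, adjusted p = 2.47e-07). Sat1, which acetylates polyamines, rose from 29.6 ± 3.31 to 66.9 ± 2.01 FPKM (adjusted p = 2.60e-07). Cbs of transsulfuration rose from 1.46 ± 0.388 to 5.01 ± 0.803 FPKM (adjusted p = 1.29e-05) and Nampt of NAD salvage from 12.9 ± 1.33 to 24.9 ± 4.16 FPKM (adjusted p = 6.61e-05). Igf1 fell from 24.2 ± 3.98 to 11.4 ± 1.78 FPKM (adjusted p = 3.51e-05). In none of the single genes above did the groups overlap.

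Tmem123 had 2 levels among controls, with replicates 1 to 6 at 65.6, 8.31, 66.3, 71.8, 9.35 and 66.9 FPKM. The fasted libraries were at 4.69 to 10.5 FPKM (log2 difference -1.94 ± 0.54, adjusted p = 0.0159). The call was lost with adipocyte covariates (-1.97, adjusted p = 0.1502).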
